A study of Mus musculus with 65 samples.

How the data were processed

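RNA sequencing had been done on poly-A RNA of 63 leukemic libraries and 2 libraries of normal granulocyte-macrophage progenitors (GMPs) from mouse bone marrow, as 75-bp paired reads from TruSeq libraries, per the labels' protocols. Reads were aligned to mm10 with TopHat2 and analysed with DESeq2, per the submitters' processing notes, which give no versions. The deposited values are raw gene counts, 1 file per library, with 39017 Ensembl gene IDs each, per the submitters' processing notes and the file headers. Each library's leukemic burden was taken from the labels as a percent of bone marrow cells, per the labels. How cells were sorted is not stated in the labels.

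Libraries were grouped by recipient, clone colour and time point from the labels, giving 18 leukemic groups of 2 to 5 libraries, here called lines, and the GMP group. Time points were T1 (no numbered recipient), T2 (day 65), T3 (day 88) and T4 (day 98). Lines of the same colour and recipient at successive times form a line of descent. All of M784 GFP, M784 Sapphire T4 and GMP have library numbers in the 4000s (13 libraries), the other 52 in the 1000s. The groups, the comparisons, the tests, the gene lists and most alternatives were fixed before the data were examined.

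Gene symbols, coordinates and biotypes came from GENCODE M21 (GRCm38, the assembly also named mm10), whose build may differ from the one used upstream. Of the IDs, 37693 matched, and the 1324 without a symbol held 0.1987% to 0.2853% of a library's counts. In all, 28 IDs shared a symbol with another and 13002 had no count in any library. Total counts were 10.6 M to 63.4 M, with a median of 25.4 M. Over 85 pairs of libraries within groups, chi-square per degree of freedom ran from 3.43 to 150.11 where counting noise alone gives 1, and the correlation of log2 CPM from 0.9757 to 0.9952.

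Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and 1 robust quasi-likelihood model with a mean for each of the 19 groups gave the 16 contrasts between libraries over 15741 genes. The interaction test asked whether the T3 minus T2 change differed between the 6 lines of descent, as an F test over 5 differences. For comparisons across lines, counts were summed within each line so that 1 line is 1 unit: T2 or T3 against T1 with colour as a covariate, T3 against T2 and T4 against T3 with line of descent as a block, and the slope on burden with colour as a covariate, per 10 points. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. A standard error is the log2 fold change divided by the square root of its F statistic. CPM values are counts scaled to library sizes after TMM, computed here, with SD over libraries or lines, and log2 CPM has a prior count of 2. The labelled burden was compared by exact two-sided permutation of the difference of means, adjusted over 9 comparisons, and correlations with burden over lines by 1e+05 permutations.

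Sets of genes were tested with camera in limma 3.58.1 at its preset correlation of 0.01 on log2 CPM, adjusted over 32 lists within each comparison, of which 7 hold markers of other cell types. The same test with a correlation estimated from the data and the rotation test fry were run beside it. For each list the text gives the members called among all genes and the number called when adjusted over the list alone. Of 672 tests of lists, 242 passed with the preset correlation and 4 with an estimated one: erythroid, B cell and mast cell markers against burden and sex-linked genes between recipients in Sapphire cells. A list score is the mean over members of log2 CPM centred per gene.

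Named genes followed a rule fixed in advance. In each comparison they are the genes with a symbol, apart from gene models, pseudogenes and immune receptor segments, with an adjusted p under 0.05, at least 2-fold change and a mean log2 CPM of at least 2. The 8 higher and 8 lower with the smallest p were taken, or 4 and 4 for colours, recipients and changes within lines, and no fold minimum was set for the burden slope. Up to 4 members with the smallest p of each list that passed were added, with a panel of 11 genes reported in every comparison: Hoxa9, Meis1, Hoxa10, Myc, Kit, Cd34, Mpo, Csf1r, Cxcr4, Itgam and Cdkn2a. Some genes that the rule names are not reported here. Where a gene had no count in a group, the fold is a bound against a floor of 3 counts over the group.

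Of the contrasts between libraries 5 of 16, and all 5 comparisons across lines, were tested on simulated counts with 200 genes changed by known folds, and the interaction test was not. In those 5 between libraries, 74.6% to 94% of 1.5-fold, 97% to 100% of 2-fold and 100% of 4-fold changes were recovered, with 2.49% to 6.7% false among the calls. Across lines, 2-fold changes were recovered in 62.7% for T2 against T1, 41.8% for T3 against T1, 74.6% for T3 against T2, 83.6% for T4 against T3 and 98.5% for burden. Chromosome values are medians over genes of the log2 ratio between line means, for 9928 genes, with bootstrap intervals over genes.

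Alternatives were DESeq2 1.42.0, limma-trend, other scalings and filters, fits with only the groups compared, leaving out each library or line, leaving out the 4000s and libraries as units. Chosen after seeing the data were fits without genes of chromosomes 6, 12, 15 and Y, without 2 libraries that stood apart, with the Erythroid score as a covariate, with line of descent as a block for burden, and the correlation of that score with burden without the 2 lines of most extreme burden and with both centred within lines of descent. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. No library was left out.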

Results

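Gene expression was measured by RNA sequencing in 65 libraries from a mouse model of acute myeloid leukemia. Granulocyte-macrophage progenitors (GMPs) of male donors were transformed with a retrovirus carrying the MLL-AF9 fusion gene, and cloned cells marked with the fluorescent proteins iRFP, GFP or Sapphire were pooled and transplanted. Leukemic cells were sampled before any numbered recipient (T1) and from the recipients M784, M798 and M800 at day 65 (T2), day 88 (T3) and day 98 (T4). Secondary lines were made from each sample, and the labels give the leukemic burden of each library's bone marrow as a percentage. The 63 leukemic libraries fall into 18 groups of 2 to 5, here called lines, each defined by recipient, clone colour and time point, and 2 libraries of normal GMPs form the remaining group. Consecutive lines of the same colour and recipient are called a line of descent. Total deposited counts ranged from 10.6 M to 63.4 M per library, with a median of 25.4 M. The labels do not say which libraries came from separate mice or cultures, so p-values measure the spread between these samples.

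Growth of the lines, the outcome named in the study's title, was given by the labelled burden. At T1 the burden averaged 28.6% ± 11.1 (SD, n = 3) in iRFP, 5.78% ± 1.70 (n = 3) in GFP and 24.3% ± 11.8 (n = 4) in Sapphire libraries. Between T2 and T3 the mean moved from 27.9% ± 12.9 to 74.3% ± 7.57 in M784 Sapphire (n = 4 and 4; difference 46.4 points, exact permutation p = 0.0286), from 47.2% ± 14.2 to 91.6% ± 3.63 in M798 GFP (n = 4 and 5; 44.4 points, exact p = 0.00794) and from 61.1% ± 17.2 to 90% ± 1.23 in M800 iRFP (n = 5 and 4; 28.9 points, exact p = 0.0159). M784 GFP went from 18.8% ± 4.47 to 86.5% ± 5.63 and M798 iRFP from 1.14% ± 0.997 to 21.7% ± 9.05. Both are comparisons of 3 against 3, in which the exact p of 0.1 is the smallest possible. M798 Sapphire had the lowest burden at T3, 3.73% ± 4.10 against 5.87% ± 3.88 at T2 (n = 3 and 3; exact p = 0.6). From T3 to T4 the mean differed by 20.7 points in M784 Sapphire (exact p = 0.0571), 8.8 points in M784 GFP (exact p = 0.2) and 7.15 points in M800 iRFP (exact p = 0.0286). After Benjamini-Hochberg adjustment over the 9 two-sided tests the lowest exact p was 0.0643, so none passed. All libraries of M784 Sapphire T4 carried 95% and both of M784 GFP T4 carried 95.3%, one shared label per group, and the 4 libraries of M800 iRFP carried 2 distinct labels at T4 and 3 at T3. The exact p counts each library, so where libraries share 1 measurement it may be too small.

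**Figure D1:**
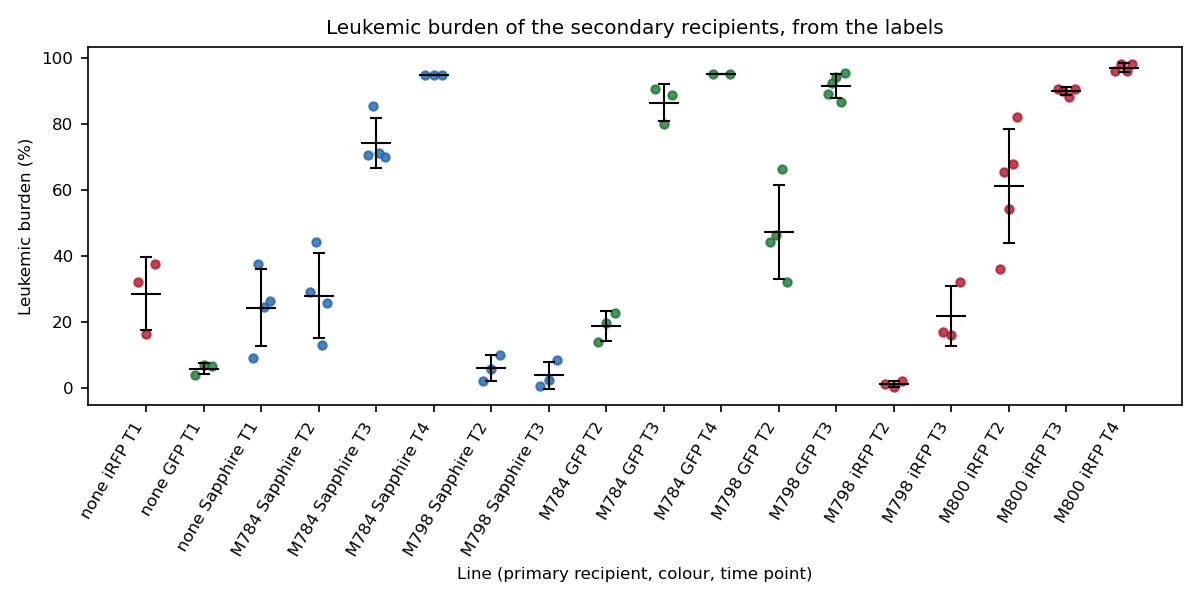
Labelled leukemic burden (percent) of each library by line; points are libraries and bars are means ± SD. M798 Sapphire stayed under 10% at both time points, while the T4 lines lay at 95% or above.

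Leukemic cells at T1 were first set against normal GMPs, the cell type the leukemia was made from. Homeobox genes of MLL-rearranged leukemia were far higher in the leukemic libraries. Hoxa10 (chromosome 6, 52231197 to 52240854 on the minus strand, GRCm38) measured 288 CPM ± 58.5 (SD, n = 10) against 0.593 ± 0.155 (n = 2), a log2 difference of 8.88 ± 0.17 (SE). Hoxa9 measured 242 CPM ± 74.9 against 16.8 ± 1.73, and Meis1, a Hox cofactor, 154.5 ± 24.8 against 18.8 ± 3.30. The fetal RNA-binding protein Igf2bp3 (70.25 CPM ± 10.7 against 0.385 ± 0.118) and the ephrin receptor Epha7 (354 ± 34.6 against 14.75 ± 0.112) were also among the genes with the smallest p. Progenitor genes were lower. The stem and progenitor surface protein Cd34 fell from 606 CPM ± 8.82 in GMPs to 3.27 ± 1.86, the receptor Kit from 454 ± 4.56 to 158 ± 19.6, and the adhesion receptor Adgrg1 from 603 ± 5.67 to 19.55 ± 4.39. The senescence gene Cdkn2a had no count in either GMP library and a mean of 1.65 CPM at T1, at least 16.2-fold higher against a floor of 3 counts over both GMP libraries.

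In the HoxA program list 12 of 20 measured genes rose and 5 fell at T1 relative to GMP, the same counts as adjusted over the list alone (camera adjusted p = 0.00423). One of those that fell was the survival gene Bcl2, at 6.46 CPM ± 2.31 against 106 ± 0.523. Of 18 stem and progenitor genes 2 rose and 14 fell (adjusted p = 0.0023), and the list-alone counts were equal. Adjusted p was 0.443 with an estimated correlation for both lists. Late granulocyte genes went up, 15 of 18 with 1 lower (alone equal, adjusted p = 0.0023), such as Cd177, a neutrophil surface protein, at 547 CPM ± 203 against 8.22 ± 0.185. Primary granule genes of early promyelocytes fell in 9 of 12 and rose in 3 (alone equal, adjusted p = 0.0228), with myeloperoxidase, Mpo, at 5889 CPM ± 2410 against 29080 ± 808 and Ms4a3 at 25.2 ± 14.2 against 1187 ± 89.6. Both granule lists had an adjusted p of 0.516 with an estimated correlation. Mitotic genes rose in 20 of 24, as did the proliferation marker Mki67 at 1256 CPM ± 187 against 469.5 ± 41.7 (alone 20, adjusted p = 0.0013, and 0.547 as adjusted p with an estimated correlation). All 20 respiratory chain genes fell, as did 24 of 25 ribosomal protein genes and 9 of 11 MHC class II genes (alone 20, 24 and 9, adjusted p = 1.66e-08, 4.21e-07 and 0.00591; adjusted p = 0.443, 0.516 and 0.443 with an estimated correlation).

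Markers of other cells moved as well. Erythroid markers were higher at T1 in 15 of 16 genes (alone 15, adjusted p = 0.0164; adjusted p = 0.547 with an estimated correlation). The red cell anion exchanger Slc4a1 measured 207 CPM ± 117 against 11.7 ± 3.795. Mast cell and basophil markers were lower in 10 of 15 (alone 9, adjusted p = 0.00344; 0.494 as adjusted p with an estimated correlation), with the mast cell carboxypeptidase Cpa3 at 2.23 CPM ± 0.966 against 174.5 ± 0.78. In all, 11755 of 15741 genes differed at adjusted p under 0.05 in edgeR's quasi-likelihood test, 6170 higher and 5585 lower, of which 6135 differed at least 2-fold. The median over all genes was 0.11 (log2). GMP libraries were numbered in the 4000s and T1 libraries in the 1000s, and the mitochondrial share of counts was 4.87% and 5.02% in GMP against 1.55% to 2.44% at T1. Within the 4000s, M784 GFP at T2 against GMP gave 11060 genes, and Slc4a1 was not called there (log2 −0.16, adjusted p = 0.808). Those T2 libraries had mitochondrial shares of 3.039% to 3.23%, so they do not match GMP in this share. In the leukemic library M784 GFP T3 replicate 3 it was 4.563%.

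Comparison of the 3 colours at T1 asked how clones of the same pre-leukemic line differed. In iRFP cells Prickle3, a planar polarity gene, measured 15.7 CPM ± 0.815 (SD, n = 3) against 0.786 ± 0.199 (n = 3) in GFP cells, and the Polycomb-group gene Sfmbt2 11.5 ± 1.65 against 0.759 ± 0.234. The adhesion gene Sdk1 was at 2.395 CPM ± 0.567 against 46.8 ± 13.2, and Mpo at 9219 ± 585 against 4888 ± 837. Sapphire cells had little Six4, a homeobox factor, 1.46 CPM ± 0.119 (n = 4) against 36.15 ± 2.78 in GFP and 66.0 ± 4.25 in iRFP cells, and little Myo18b, an unconventional myosin, 13 ± 2.17 against 154 ± 24.8 and 289 ± 23. Hoxa9 was highest in Sapphire cells, 319 CPM ± 37.1 against 224 ± 6.36 in GFP and 157 ± 3.57 in iRFP cells, whereas Mpo was lower there, at 4143 ± 759, than in iRFP cells (log2 difference −1.15 ± 0.11, SE). Hoxa9 lies on chromosome 6, whose genes stood 0.47 (log2) higher in the median in the Sapphire line than in the other T1 lines. Its excess there was not separated from that shift.

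Ribosome biogenesis genes under Myc were lowest in GFP cells. Against them 9 of 22 rose in iRFP and 17 rose with 1 lower in Sapphire cells (alone 11, and 20 with 1 lower, adjusted p = 1.42e-06 and 2.38e-08; adjusted p = 0.61 and 0.57 with an estimated correlation). The nucleolar methyltransferase Nop2 measured 127 CPM ± 3.15 in Sapphire against 70.9 ± 4.53 in GFP cells. Interferon response genes were lower in Sapphire than in iRFP cells in 19 of 29 (alone 20, adjusted p = 4.7e-05; adjusted p = 0.712 with an estimated correlation), such as Ifit2 at 16.9 CPM ± 1.85 against 37.5 ± 1.36. Monocyte and macrophage genes were lower in 12 of 22 with 2 higher (alone equal, adjusted p = 0.000686; adjusted p = 0.712 with an estimated correlation), including F13a1 at 60.2 CPM ± 12.2 against 294 ± 11.5. Erythroid markers were lower in iRFP than in GFP cells in all 16 genes and higher in Sapphire than in iRFP cells in 13 (alone 16 and 14, adjusted p = 3.16e-11 and 0.000458; adjusted p = 0.381 and 0.712 with an estimated correlation). The erythroid factor Klf1, for instance, measured 4.795 CPM ± 1.72 in iRFP, 26.2 ± 10.5 in GFP and 15.3 ± 3.94 in Sapphire cells. B cell markers were likewise lower in iRFP than in GFP cells in 8 of 15 genes and higher in Sapphire than in iRFP cells in 10 (alone 9 and 14, adjusted p = 0.0132 and 0.00222; adjusted p = 0.832 and 0.712 with an estimated correlation). Immediate early genes, which also respond to handling of samples, were higher in Sapphire than in iRFP cells in 7 of 18 (alone 7, adjusted p = 0.00258; adjusted p = 0.712 with an estimated correlation), such as Dusp1 at 67.5 CPM ± 41.7 against 13.25 ± 5.575. The edgeR test called 3332 genes between iRFP and GFP (1514 higher), 5613 between Sapphire and GFP (2361 higher) and 6466 between Sapphire and iRFP (3040 higher). With the Erythroid score as a covariate, an alternative chosen after seeing the data, the first count was 1562. Each colour at T1 is 1 line, so these tests cover the spread between libraries of those lines.

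**Figure D2:**
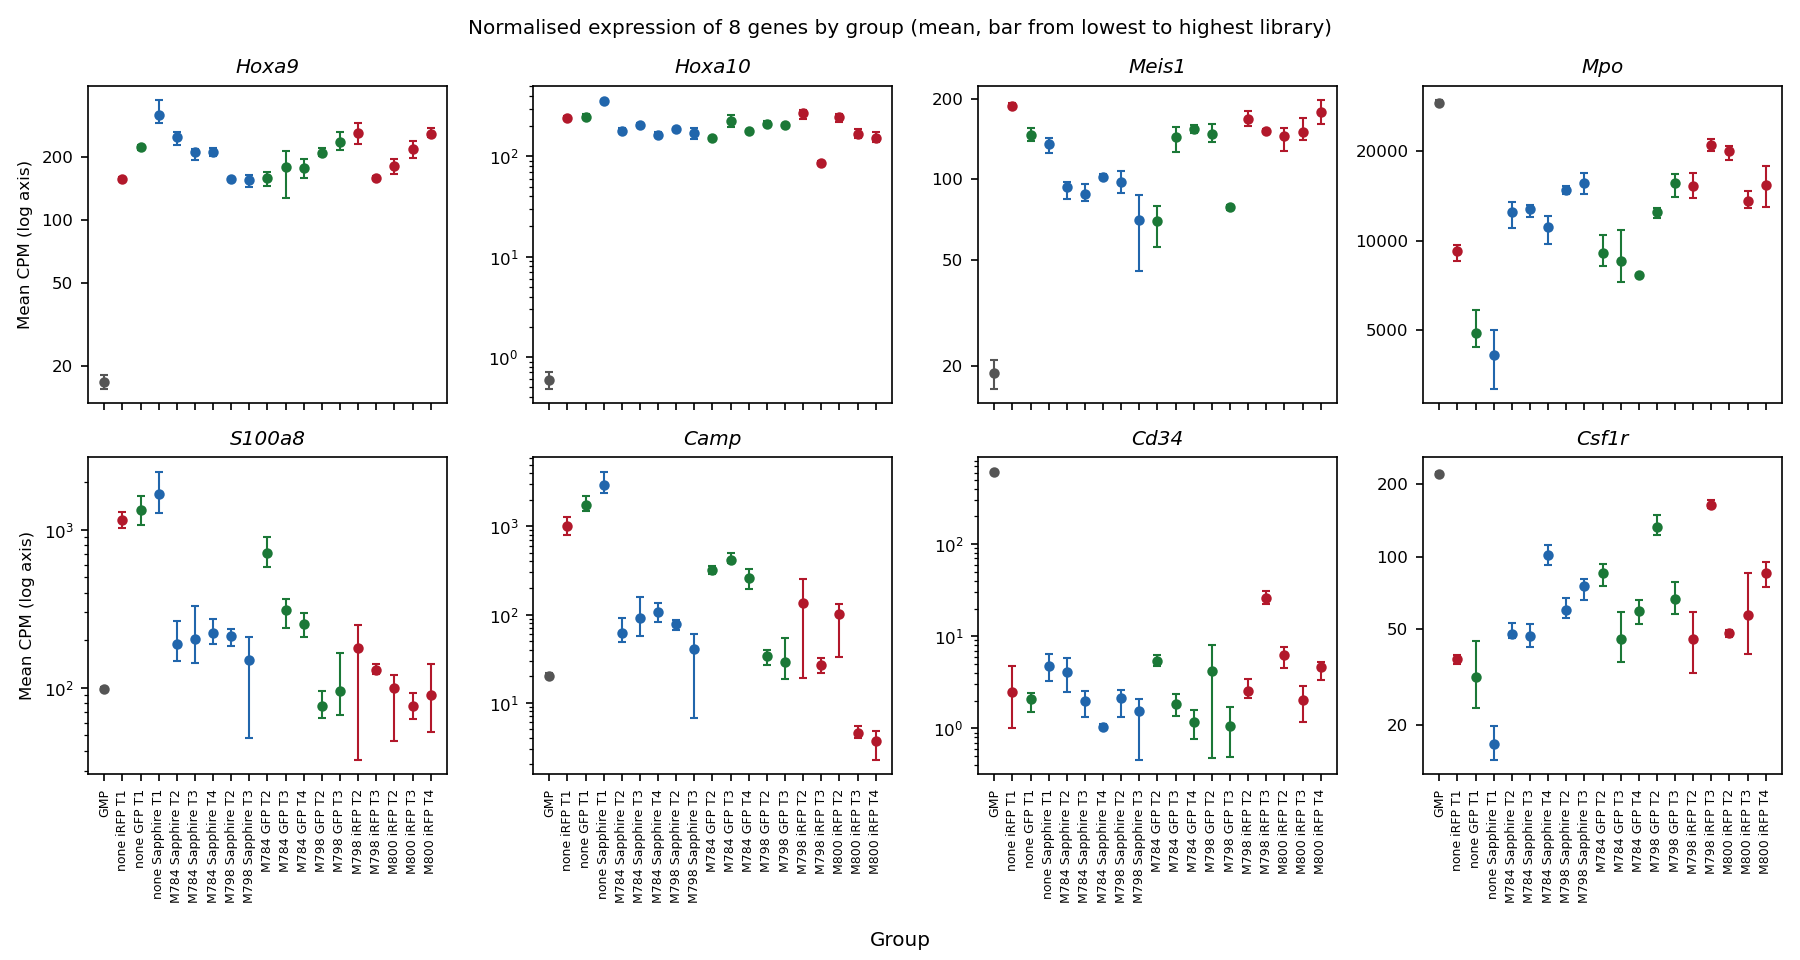
Mean CPM (log axis) of 8 genes in the 19 groups, with bars from the lowest to the highest library and colours by clone and grey for GMP; "none" marks the T1 lines, which have no recipient. Hoxa10 was lowest among leukemic lines in M798 iRFP T3 (85.1 CPM), and Cd34 was far lower in each leukemic line than in GMP.

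The 6 lines from recipients at T2 were compared with the 3 lines at T1, each line as 1 sum of counts with colour as a covariate. The 6 lines came from the recipients M784, M798 and M800 only. Recipient was not a term of the fit, so lines sharing a recipient were counted as independent. Mpo rose from 6173 CPM ± 2802 (SD over lines, n = 3) to 14330 ± 3851 (n = 6), and Elane, neutrophil elastase, from 5111 ± 722 to 7960 ± 510. The neutrophil granule peptide Camp fell from 1922 CPM ± 1002 to 124 ± 101, and Cebpe, a factor of terminal granulocyte differentiation, from 232 ± 70.4 to 86.0 ± 20.9. Egln1, the oxygen-sensing prolyl hydroxylase (36.4 CPM ± 9.54 against 11.0 ± 4.16; log2 1.74 ± 0.12, SE) was among the genes that rose with the smallest p. Gca, a granulocyte calcium-binding protein (25.9 ± 4.65 against 107 ± 17.9), and Cd33 (37.5 ± 26.0 against 180 ± 102) were among those that fell. Myc itself rose from 133 CPM ± 32.3 to 194.5 ± 42.8. It lies on chromosome 15, whose genes were 0.53 (log2) higher in the median in the M784 and M798 lines than at T1. In those lines its rise cannot be told apart from that shift. The M800 iRFP T2 line lacked the shift (chromosome 15 median centred over lines −0.563, and −0.562 in T1 iRFP). There Myc measured 206 CPM against 131.8 in T1 iRFP.

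Of the primary granule list 4 of 12 genes rose and of the late granulocyte list 5 of 18 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.00142 and 6.87e-05). Ribosome biogenesis genes rose in 6 of 22 and cholesterol synthesis genes in 5 of 18 with 1 lower (alone 13, and 13 with 2 lower, adjusted p = 6.21e-07 and 5.46e-05). Adjusted p was 0.85 with an estimated correlation for the late granulocyte list and 0.378 for the other 3. Erythroid markers were lower over T2 lines by the list test (adjusted p = 0.00115; adjusted p = 0.85 with an estimated correlation), with none of 16 genes passing in the edgeR fit, alone or among all. The edgeR test called 707 genes, 386 higher and 321 lower. These counts depended on single lines: without the T1 GFP line 1 gene was called, without T1 Sapphire 14, without M784 Sapphire 24, without M798 Sapphire 36, without T1 iRFP 255 and without M798 GFP 396.

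Against the same T1 lines, the 6 lines at T3 showed 72 changed genes, 35 higher and 37 lower. Calprotectin subunit S100a8 fell from 1375 CPM ± 284 (n = 3) to 170.5 ± 84.1 (n = 6), as did the neutrophil-expressed Stfa2 (20.9 ± 13.5 to 0.146 ± 0.0938) and Gca (105 ± 17.4 to 31.2 ± 4.22). Ifitm2, an antiviral membrane protein, rose from 64.4 CPM ± 5.59 to 148 ± 32.2, and Mcf2l, a guanine nucleotide exchange factor, from 9.34 ± 4.34 to 83.4 ± 29.9, close to its T2 mean of 84.6 ± 27.4. Late granulocyte genes passed in 1 of 18 (alone 9, adjusted p = 2.24e-06; adjusted p = 0.596 with an estimated correlation), and erythroid markers in none of 16 (alone 11 lower, adjusted p = 3.71e-08 and, with an estimated correlation, adjusted p = 0.596). Mpo stood at 14630 CPM ± 4337 against 6063 ± 2745 (adjusted p = 0.0718). For T3 vs T1 across lines, leaving out M784 Sapphire, M798 Sapphire, T1 GFP or T1 Sapphire left 0 genes in edgeR (2522, 2488, 2040 and 1996 at unadjusted p under 0.05), and omission of M798 GFP, T1 iRFP, M798 iRFP, M800 iRFP or M784 GFP gave 4, 6, 7, 432 and 526 genes. The comparison at T3 shares its 3 controls with that at T2, so the lists are not independent. Here too, lines sharing a recipient were counted as independent.

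Changes from T2 to T3 were then followed within each line of descent, over single libraries. In M784 Sapphire, the lactate dehydrogenase gene Ldhb rose from 0.708 CPM ± 0.222 (SD, n = 4) to 29.4 ± 1.74 (n = 4; log2 5.27 ± 0.23, SE). Satb1, a chromatin organizer, fell from 36.9 CPM ± 7.27 to 3.24 ± 0.763, Myc from 223 ± 21.2 to 116 ± 11.6 and Kit from 197 ± 15.6 to 131 ± 12.2, while Cdkn2a rose from 2.49 ± 0.539 to 6.12 ± 0.73. Cholesterol synthesis genes rose in 12 of 18, including Fdps (242 CPM ± 13.2 against 139 ± 23.9), and G1/S genes in 15 of 22 (alone 13 and 18, adjusted p = 2.12e-08 and 4.96e-08). Ribosomal protein genes fell in 24 of 25 and immediate early genes in 11 of 18 (alone 25 and 12, adjusted p = 1.84e-12 and 2.8e-05). For these 4 lists in turn the adjusted p with an estimated correlation was 0.232, 0.251, 0.32 and 0.345. The immediate early score was 1.805 at T2, the highest of the 19 groups, and 0.563 at T3. These genes also respond to handling of samples, which was not tested. Erythroid markers fell in 14 of 16 and B cell markers in 10 of 15 (alone 15 and 10, adjusted p = 1.22e-13 and 0.00521; adjusted p = 0.0947 and 0.516 with an estimated correlation). All 4 Y-linked genes rose (alone 4, adjusted p = 8.32e-07; adjusted p = 0.0947 with an estimated correlation), Ddx3y from 33.8 CPM ± 5.62 to 54.4 ± 4.29. The test called 4224 genes, 2154 higher, and 1340 with the Erythroid score as a covariate (872 higher).

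M798 Sapphire, whose burden stayed low, differed least between T2 and T3. Ldhb rose here too, from 2.78 CPM ± 1.62 (n = 3) to 42.3 ± 2.18 (n = 3), as did the kinesin Kifc3 (4.56 ± 0.537 to 20.7 ± 2.59), the arsenite methyltransferase As3mt (4.28 ± 0.778 to 18.5 ± 7.56) and the p53 target Cdkn1a (16.05 ± 0.604 to 30.95 ± 2.61). The ceramide galactosyltransferase Ugt8a fell from 41.4 CPM ± 5.42 to 18 ± 2.99, cyclin D2 (Ccnd2) from 34.1 ± 2.62 to 17.1 ± 0.61 and Meis1 from 97.9 ± 9.53 to 70.7 ± 22.3. In all 112 genes changed, 82 higher and 30 lower, and 73 with only these 6 libraries in the fit. Among the 9 lists that passed, Cdkn1a in the p53 list and H2-Ob in the MHC class II list were the members called (alone 2 and 2, adjusted p = 0.000605 each; adjusted p = 0.242 and 0.477 with an estimated correlation).

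In M784 GFP, Meis1 rose from 69.5 CPM ± 12.4 (n = 3) to 144 ± 16.2 (n = 3), Hoxa10 from 152 ± 4.97 to 223 ± 32.9, the opioid precursor Penk from 63.7 ± 20.5 to 331 ± 48.2 and Sgce from 2.965 ± 1.33 to 25.2 ± 2.71. Monocyte genes went down, 11 of 22 with 3 higher (alone equal, adjusted p = 0.00657; adjusted p = 0.431 with an estimated correlation), such as Irf8, a factor of monocyte fate, from 111 CPM ± 21.3 to 41.1 ± 2.6, and Ccr2 from 46.1 ± 11.1 to 15.2 ± 2.85. All 4 Y-linked genes of the sex-linked list fell (alone 4, adjusted p = 5.09e-07; 0.0752 as adjusted p with an estimated correlation), Ddx3y from 77.0 CPM ± 6.24 to 37.2 ± 7.41. Erythroid, B cell and mast cell markers fell in 14 of 16, 13 of 15 and 10 of 15 (alone 15, 13 and 10, adjusted p = 5.02e-11, 3.17e-07 and 1.61e-05; adjusted p = 0.135, 0.205 and 0.189 with an estimated correlation), with Hbb-bs at 2.48 CPM ± 0.876 against 37.5 ± 29.2. The edgeR test called 4706 genes, 2547 higher and 2159 lower; with the Erythroid score it called 1164 (758 higher), and with only these 6 libraries in the fit 1372 (581 higher). At T3 replicate 3 stood apart with a mitochondrial share of 4.56%, and without it 3304 genes were called. It had 16002 genes with a count. The GMP libraries were close to it in both measures, with 4.865% and 5.02%, and 15965 and 16256 genes. What they share was not tested.

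M798 GFP lost expression of Tcf19 (15.5 CPM ± 1.2, n = 4, to 0.644 ± 0.145, n = 5; log2 −4.60 ± 0.11, SE), Dmrtb1 (367 ± 17.5 to 19 ± 1.79) and the myeloid and neural factor Mef2c (32.0 ± 1.25 to 6.86 ± 0.494). Meis1 fell from 148 CPM ± 10.2 to 78.5 ± 1.39, Bcl2 from 9.77 ± 0.65 to 3.32 ± 0.477, Csf1r from 133 ± 11.4 to 66.5 ± 7.68 and Cd34 from 4.18 ± 3.88 to 1.07 ± 0.537. With these, the HoxA program list fell in 10 of 20 and rose in 2 (alone 11 and 3, adjusted p = 0.00102; adjusted p = 0.126 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 18, primary granule genes in 9 of 12 with 1 lower, and unfolded protein response genes in 10 of 18 (alone 17, 9 with 1 lower, and 11, adjusted p = 8.7e-11, 0.000563 and 4.19e-06; adjusted p = 0.141, 0.219 and 0.208 with an estimated correlation). The chaperone Hspa5 measured 1367 CPM ± 289 against 741.5 ± 89.5 and the asparagine synthetase Asns 114 ± 8.74 against 42.2 ± 4.43. Erythroid markers fell in 14 of 16 with 1 higher, interferon response genes in 13 of 29 with 1 higher (alone equal in both, adjusted p = 1.12e-08 and 0.000234; adjusted p = 0.191 and 0.334 with an estimated correlation). The count was 5043 genes, 2447 higher, and 2141 with the Erythroid score as a covariate.

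M798 iRFP lines at T2 and T3 had unlike profiles. Over 10015 genes centred on the mean of all lines they correlated at −0.219, against 0.415 to 0.9 for the other 8 consecutive pairs, and the centred medians of chromosomes 6 and 12 were 0.439 and 0.404 at T2 but −0.006 and −0.095 at T3, so the values compare the lines without showing that one descends from the other. By the same correlation the line nearest M798 iRFP T2 was T1 Sapphire (0.166), and that nearest M798 iRFP T3 was M798 Sapphire T3 (0.195). Hoxa10 fell from 268 CPM ± 27.8 (n = 3) to 85.1 ± 3.75 (n = 3), Hoxa9 from 261 ± 30.6 to 159 ± 3.26, and Igf2r, the receptor that clears insulin-like growth factor 2, from 325 ± 25.8 to 0.934 ± 0.245. Csf1r, the macrophage colony-stimulating factor receptor, rose from 45.5 CPM ± 12.9 to 164 ± 6.72, Kit from 173 ± 17.8 to 379 ± 13.5 and Cd34 from 2.57 ± 0.762 to 26.1 ± 4.57, while Meis1, Cxcr4 and Itgam were not called (adjusted p = 0.344, 0.512 and 0.65). Sdk1 rose from 1.305 CPM ± 0.97 to 100.2 ± 5.56 and Col6a6, a collagen chain, from 2.61 ± 0.455 to 98.8 ± 6.24. Mitotic genes rose in 21 of 24 and erythroid markers fell in 11 of 16 (alone equal, adjusted p = 1.55e-06 and 0.0116; adjusted p = 0.962 each with an estimated correlation). Hbb-bs nevertheless measured 369 CPM at T3 against 492.5 at T2, among the higher values of any line. In all 6553 genes changed, 3062 higher and 3491 lower.

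In M800 iRFP, As3mt rose from 0.314 CPM ± 0.211 (n = 5) to 21.7 ± 2.09 (n = 4) and Tcf24 from 0.424 ± 0.11 to 70.2 ± 24.5, while the Rac exchange factor Tiam1 fell from 50.1 ± 4.22 to 9.74 ± 2.04. Kit fell from 285 CPM ± 12 to 161 ± 17.6, Mpo from 20020 ± 816 to 13570 ± 809 and Cd34 from 6.21 ± 1.42 to 2.05 ± 0.789. Late granulocyte genes fell in 12 of 18 with 2 higher (alone 13 and 2, adjusted p = 0.000502), with Camp at 4.49 CPM ± 0.669 against 102 ± 40.7 and Ngp at 5.18 ± 2.1 against 145 ± 58.3. Ribosomal protein genes rose in 14 of 25 (alone 20, adjusted p = 0.00922). Adjusted p was 0.938 with an estimated correlation for each of these lists. The edgeR count was 6793 genes, 3265 higher, and 5644 to 7463 when each library was left out in turn.

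**Figure D3:**
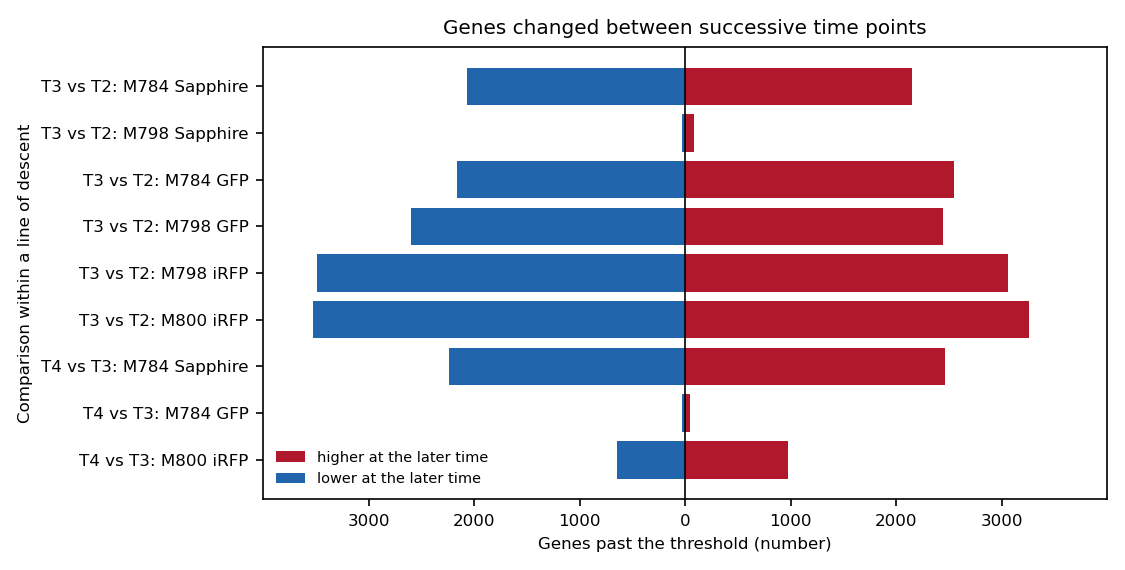
Number of genes higher (above 0) and lower (below 0) at adjusted p under 0.05 in each T3 against T2 and T4 against T3 comparison within a line of descent. Counts ran from 72 in M784 GFP T4 against T3 to 6793 in M800 iRFP T3 against T2.

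The changes differed between lines of descent. Testing the 5 differences among the 6 changes, edgeR called 11216 of 15741 genes (71.3%), including all 11 genes of the fixed panel, from Hoxa10 (adjusted p = 8.29e-23) to Cxcr4 (0.0148). Meis1, for example, rose in M784 GFP and fell in M798 GFP. Pearson correlations of the log2 changes over genes between the 15 pairs of lines ran from −0.09 to 0.31 and Spearman correlations from −0.17 to 0.23, as a description over genes, which are not independent replicates. Cyclin D2, chosen after its values were seen, was the 1 gene lower in all 6 lines, and no gene was higher in all 6. Across the 6 pairs of line sums, with line of descent as a block, edgeR called 0 of 15195 genes, with 1060 at unadjusted p under 0.05, and DESeq2 called 131. List tests on that fit called erythroid markers lower (none of 16 passing, alone 12; adjusted p = 1.52e-13; adjusted p = 0.29 with an estimated correlation) and mast cell and late granulocyte genes lower (alone 10 of 14 and 4 of 18, adjusted p = 1.97e-07 and 3.31e-07; adjusted p = 0.29 each with an estimated correlation).

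Samples from T4 covered 3 lines of descent. In M784 Sapphire, Kit rose from 131 CPM ± 12.2 (n = 4) to 262 ± 17.7 (n = 3), Csf1r from 46.8 ± 4.24 to 102 ± 9.82 and Siglecf, a sialic acid receptor, from 34.45 ± 3.34 to 124 ± 12.3. Monocyte genes rose in 11 of 22 (alone 12, adjusted p = 0.000206), and mitotic genes fell in 13 of 24 and unfolded protein response genes in 10 of 18 (alone 15 and 10, adjusted p = 3.07e-05 and 8.96e-05). For these 3 lists the adjusted p was 0.373, 0.576 and 0.373 with an estimated correlation. Erythroid and mast cell markers fell in 14 of 16 and in 10 of 15 with 2 higher (alone 14, and 11 with 2 higher, adjusted p = 3.97e-16 and 7.24e-05; adjusted p = 0.0944 and 0.298 with an estimated correlation), with Hbb-bs at 1.17 CPM ± 0.0926 against 40.6 ± 21.7. Stroma markers rose in 4 of 13 (alone 4, adjusted p = 0.0125; 0.373 as adjusted p with an estimated correlation). The count was 4706 genes, 2464 higher, and 2093 with the Erythroid score. Its T4 libraries were numbered in the 4000s and its T3 libraries in the 1000s, so the number series and the time point cannot be told apart here. The titles of these T4 libraries read S4 where other Sapphire titles read S. The T3 and T4 profiles of M784 Sapphire correlated at 0.415, against 0.886 in M784 GFP and 0.9 in M800 iRFP. Descent of this T4 line from the T3 line is therefore assumed.

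M784 GFP changed little from T3 to T4, with 72 genes called, 45 higher. Tcf24 fell from 15.6 CPM ± 4.65 (n = 3) to 4.71 ± 0.0935 (n = 2), and Mtus2 rose from 16.3 ± 2.87 to 37.3 ± 5.35. Single libraries moved this count: it was 18 without T4 replicate 1, 41 without T4 replicate 2, 134 without T3 replicate 1, 253 without T3 replicate 2, 47 without T3 replicate 3 and another library that stood apart, and 1 with only these 5 libraries in the fit. Erythroid markers passed the list test with none of 16 genes called, alone or among all (adjusted p = 0.00222; adjusted p = 0.748 with an estimated correlation).

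In M800 iRFP at T4, Eya1, a phosphatase and transcriptional cofactor, fell from 32.55 CPM ± 6.2 (n = 4) to 2.65 ± 0.861 (n = 4; log2 −3.66 ± 0.14, SE), as did the retinol transporter Stra6 (35.4 ± 6.85 to 1.96 ± 0.442) and the myeloid lectin Clec12a (135 ± 37.9 to 22.2 ± 5.21). Kit rose from 161 CPM ± 17.6 to 234 ± 24.7 and Csf1r from 57.2 ± 19.9 to 85.85 ± 9.05. Glycolysis genes rose in 8 of 17, ribosome biogenesis genes in 7 of 22 and cholesterol synthesis genes in 7 of 18 (alone 8, 13, and 9 with 1 lower, adjusted p = 1.14e-05, 1.14e-05 and 7.94e-05; adjusted p = 0.488 each with an estimated correlation). Interferon response genes fell in 7 of 29 (alone 12, adjusted p = 3.55e-05; adjusted p = 0.592 with an estimated correlation), where the T3 libraries varied widely, as in Gbp2 at 18.4 CPM ± 25.3 against 4.06 ± 1.52. Erythroid and mast cell markers also passed as lower, with 1 of 16 and 2 of 15 genes called (alone 1, and 3 with 1 higher, adjusted p = 0.00155 and 0.00631; adjusted p = 0.592 and 0.488 with an estimated correlation). The count was 1619 genes, 972 higher. It was 3840 without T3 replicate 3, 753 without T3 replicate 1, 904 and 847 without T3 replicates 2 and 4, 926 without T4 replicate 3, and 267 with only these 8 libraries in the fit (122 higher). In that fit 3 of 35 splits of the 8 libraries, the labels included, gave as many genes (highest other 846), so chance is not excluded for these changes. Over the 3 pairs of line sums edgeR called 0 of 15028 genes, with 738 at unadjusted p under 0.05, and DESeq2 called 65. The count depended on the lines included, with 7 genes without M800 iRFP, 50 without M784 GFP and 93 without M784 Sapphire.

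Lines of the same colour in different recipients were compared over T2 and T3 together. Chromosome 12 medians centred over lines were 0.539 in M800 iRFP T2 and 0.404 in M798 iRFP T2. At T3 they were 0.478 in M800 iRFP but −0.095 in M798 iRFP, so a shared colour does not show a shared clone. Sapphire cells of M784 had more Homer1, a scaffold protein (163 CPM ± 20.9, n = 8, against 18.3 ± 2.12, n = 6, in M798), and less of the transmembrane gene Tmem178 (8.97 ± 5.8 against 213 ± 23.3) and cathepsin F, Ctsf (1.09 ± 0.796 against 38.4 ± 15.9). Kit was at 164 CPM ± 37.6 against 278 ± 19.2, and Hoxa9 at 231 ± 24.5 against 156 ± 7.04. Immediate early genes were higher in M784 in 15 of 18 and cholesterol synthesis genes in 15 of 18 (alone 16 each, adjusted p = 2.21e-08 each; adjusted p = 0.29 each with an estimated correlation). The immediate early score was 1.805 at T2 and 0.563 at T3 in M784 Sapphire, against −0.342 and −0.527 in M798 Sapphire. Handling of samples, to which these genes also respond, was not separated from recipient. All 4 Y-linked genes were lower in M784 (alone 4, adjusted p = 4.16e-08; adjusted p = 0.0362 with an estimated correlation), Ddx3y at 44.1 CPM ± 11.9 against 72.2 ± 3.96, with a log2 difference of −1.02 at T2 alone and −0.47 at T3 alone. Erythroid markers were lower in 9 of 16 with 1 higher (alone 10 and 1, adjusted p = 0.000531; adjusted p = 0.557 with an estimated correlation). The test called 4764 genes, 2214 higher, with 1936 at T2 alone.

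The comparison of iRFP cells of M800 with M798 pooled T2 and T3 lines, whose profiles were unlike in M798. Ldhb (0.616 CPM ± 0.246, n = 9, against 73.6 ± 16.2, n = 6), Ugt8a (0.0663 ± 0.119 against 40.3 ± 30.7) and the ceramide kinase Cerk (98.9 ± 32.7 against 370 ± 47.6) were lower in M800, while Six4 (54.5 ± 29.0 against 22.5 ± 24.6) was higher. At T2 alone Six4 differed by −0.54 on the log2 scale. Erythroid and B cell markers were lower in M800 in all 16 and all 15 genes and mast cell markers in 12 of 15 (alone equal, adjusted p = 5.89e-15, 1.55e-05 and 4.91e-06; adjusted p = 0.131, 0.337 and 0.243 with an estimated correlation), with Alas2, the heme synthesis enzyme, at 0.621 CPM ± 0.259 against 48.3 ± 17.1. Late granulocyte genes were lower in 16 of 18 with 1 higher and G1/S genes in 16 of 22 with 1 higher (alone equal, adjusted p = 0.000231 and 0.000146; adjusted p = 0.541 each with an estimated correlation). The test called 9344 genes, 4673 higher, and 2311 with the Erythroid score as a covariate.

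GFP cells of M784 against M798 were higher in Mef2c (281 CPM ± 43.0, n = 6, against 18.05 ± 13.3, n = 9) and Homer1 (300.4 ± 92.8 against 18.6 ± 2.25), and lower in As3mt (0.714 ± 0.523 against 24.4 ± 4.43), Siglecf (12.7 ± 1.34 against 114 ± 64.1) and Cdkn2a (1.29 ± 0.532 against 4.80 ± 0.935). Late granulocyte genes were higher in 17 of 18 (alone 17, adjusted p = 4.13e-08; adjusted p = 0.528 with an estimated correlation), including Camp at 368 CPM ± 74.1 against 31.0 ± 11.1 and Mmp9 at 58.4 ± 44.6 against 2.16 ± 1.18. Stem and progenitor genes were higher in 11 of 18 with 1 lower (alone equal, adjusted p = 0.0316; adjusted p = 0.528 with an estimated correlation), such as the factors Hlf (5.145 CPM ± 1.88 against 0.438 ± 0.181) and Erg (9.31 ± 1.88 against 1.91 ± 0.485). Markers of other cells were higher too: B cell in 12 of 15 with 1 lower, megakaryocyte in 9 of 12 and stroma in 10 of 13 (alone equal, adjusted p = 0.00445, 0.00445 and 0.0435; adjusted p = 0.598, 0.528 and 0.528 with an estimated correlation). The count was 8933 genes, 4533 higher. Libraries of M784 GFP were numbered in the 4000s and those of M798 GFP in the 1000s, so recipient and number series cannot be told apart in this comparison.

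Expression was then related to the labelled burden over the 18 leukemic lines, with colour as a covariate. Genes of red cells fell with burden: per 10 points, Alas2 by 0.77 ± 0.09 (log2, SE) and Hba-a1 by 0.82 ± 0.10. Tal1, an erythroid factor that is a member of the stem and progenitor list, fell by 0.63 ± 0.08. The interferon-induced gene Rsad2, an antiviral enzyme, fell by 0.41 ± 0.04 per 10 points and had the smallest p (adjusted p = 0.000164). Erythroid markers fell in 15 of 16, B cell markers in 10 of 15 and mast cell markers in 9 of 14 (alone 16, 12 and 11, camera adjusted p = 8.51e-36, 6.67e-21 and 2.06e-15), and these calls held with an estimated correlation (adjusted p = 0.0194 each). Interferon response genes fell in 5 of 28 and cholesterol synthesis genes such as Idi1 rose in 4 of 18 (alone 17 and 12, adjusted p = 9.15e-10 and 1.9e-10; adjusted p = 0.11 each with an estimated correlation). By the preset correlation alone, stem and progenitor, megakaryocyte, dendritic cell, MHC class II, late granulocyte and STAT5 target lists passed too. Their called members with the smallest p were lower, such as Itga2b, Siglech, Cd74 and Ly6g. The stroma and p53 lists also passed, with Cxcl12 and Ccng1 higher. The HoxA program had no gene called, alone or among all (adjusted p = 0.878), and Hoxa9, Meis1, Myc and Mpo had slopes of 0.02 ± 0.02, 0.01 ± 0.02, −0.01 ± 0.02 and 0.01 ± 0.04.

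The edgeR test called 469 of 16623 genes, 85 higher and 384 lower with burden. The number was 834 without M784 GFP, 261 without M800 iRFP, 1020 within the 1000s (483 higher), 14 with time point as a further covariate, 1 with the Erythroid score, 8 on log2 burden, 4 for libraries within groups, 0 in edgeR with the T2 and T3 lines alone (1839 at unadjusted p under 0.05), and 900 in DESeq2 (280 higher). The mean Erythroid score of a line correlated with its burden (Pearson r = −0.925, permutation p = 1e-05, the smallest possible; Spearman correlation −0.870, permutation p = 4e-05; 18 lines). Without the 2 lines of most extreme burden r was −0.904, and within the 14 lines of the 1000s it was −0.911. Score and burden were so closely correlated that a fit holding both cannot tell their slopes apart. The 18 lines are not independent, as 15 of them are repeated time points of 6 lines of descent. With both values centred within these lines of descent r was −0.922 over the 15 lines (exact p = 0.00116 over 1728 permutations within lines of descent), and with line of descent as a block in the edgeR fit 312 genes were called, 266 lower, with 14 of 16 erythroid, 7 of 15 B cell and 3 of 14 mast cell markers among them. The block fits and the relation of the Erythroid score to burden were chosen after the slopes were seen.

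**Figure D4:**
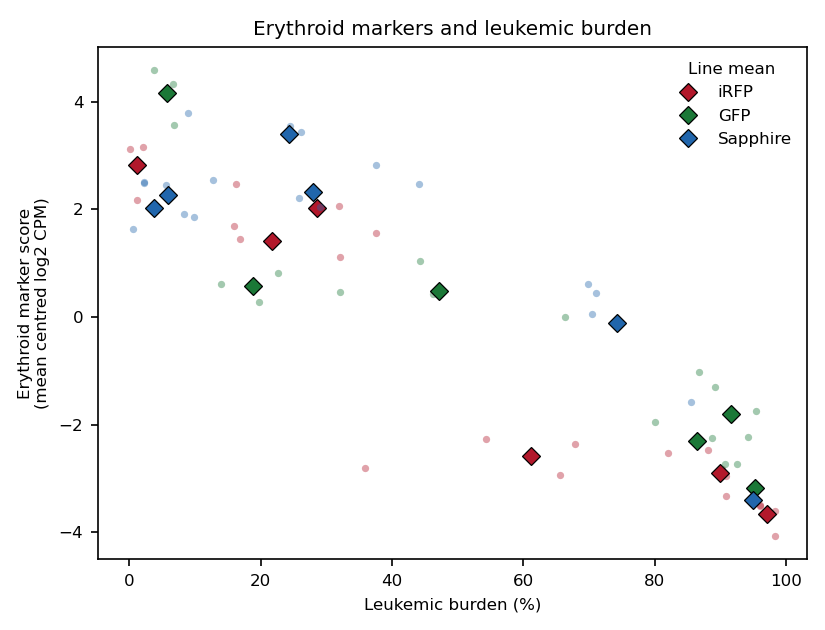
Erythroid score (mean of log2 CPM centred per gene) against labelled burden (percent); small points are libraries and diamonds are line means. The score falls as burden rises over the 18 lines (Pearson r = −0.925).

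Median expression ratios by chromosome, a summary chosen after the values were seen, differed between lines. Over 377 genes of chromosome 15, the median log2 difference between the M784 and M798 lines and the T1 lines was 0.53 (bootstrap interval 0.50 to 0.56), with 95.8% of genes higher. Over 343 genes of chromosome 12, the M800 lines were 0.54 above GMP in the median, and over 471 genes of chromosome 6 the T1 Sapphire line was 0.47 above the other T1 lines. Autosomes other than 6, 12 and 15 had medians from −0.12 to 0.06 in these 3 comparisons. Chromosome 12 differed between the T1 lines as well, with medians centred over lines of 0.505 in iRFP, 0.352 in GFP and −0.085 in Sapphire.

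**Figure D5:**
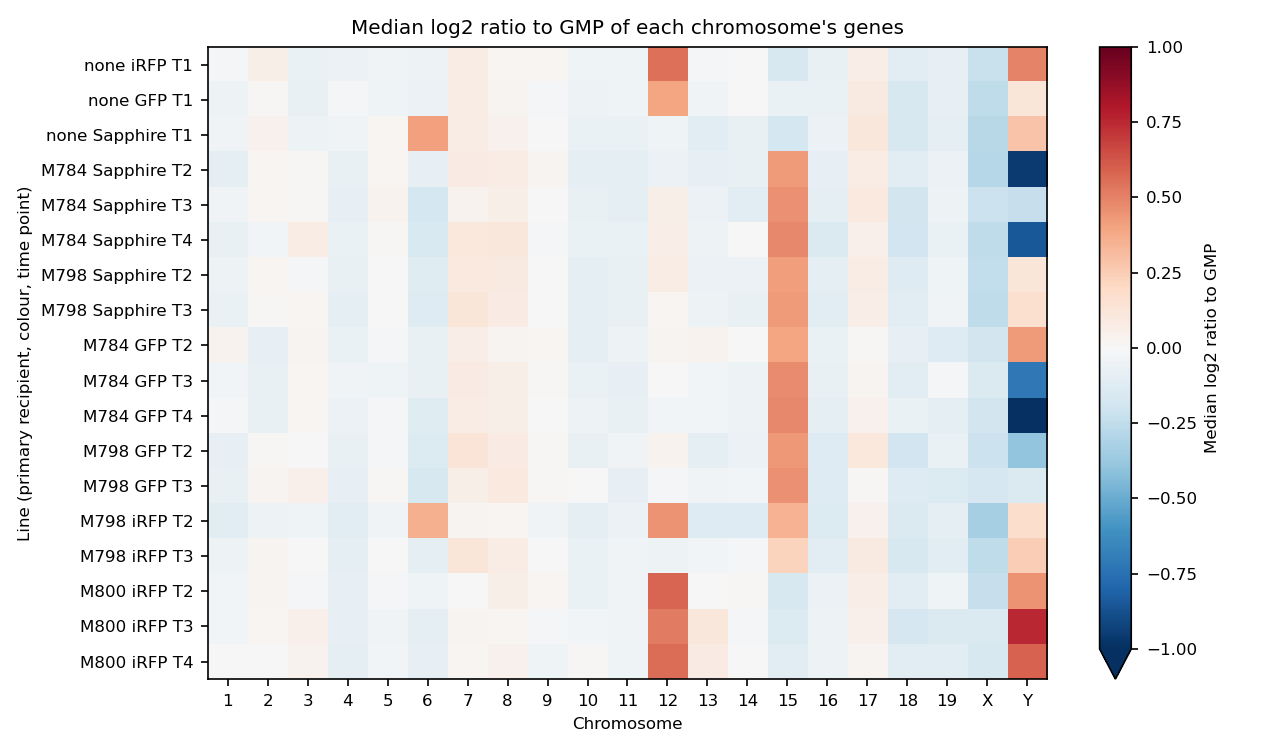
Median log2 ratio to GMP by line and chromosome, on a colour scale ending at −1 and 1. Chromosome 15 stands higher in the M784 and M798 lines, chromosome 12 in the T1 iRFP, T1 GFP, M798 iRFP T2 and M800 lines and chromosome 6 in the T1 Sapphire and M798 iRFP T2 lines; chromosome Y rests on 5 genes.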

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

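Of the tests below, those of chromosome 15 for library number series and a further copy, those of B cell and mast cell markers for time point and number series, the covariate fit with the Erythroid score and the fit without 4 chromosomes were chosen after the results were seen.

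The change from T2 to T3 differed between the 6 lines of descent for 11216 genes, among them all 11 genes of the fixed panel. Without the genes of chromosomes 6, 12, 15 and Y, 70.43% of genes were called against 71.25% with them. The calls were thus not confined to these chromosomes. Most genes lie on other chromosomes, so the share could not have fallen far. Effects of the chromosome-wide shifts on genes elsewhere were not tested, so the shifts remain open as a cause. With the Erythroid score as a covariate 10299 genes were called, which argues against erythroid content as the whole cause. The same covariate lowered several of the counts within single lines, as given above. Of 100 splits of the samples, the labels included, 1 gave as many genes as the labels (10517, against at most 3970), which argues against a chance split of these libraries. A separate course of each line remains a hypothesis, and the labels do not say which libraries of a line came from separate mice or cultures, which leaves differences between cultures untested.

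Erythroid, B cell and mast cell markers were lower in lines of higher labelled burden. With time point as a covariate the median erythroid slope per 10 points was −0.636, against −0.776 without, with a jackknife SE over lines of 0.203, and 5 of 16 members were called. The bound fixed for this list used the slope alone, without its SE. Under the bound with SE used for the lists that follow, time point and burden could not be told apart for the erythroid markers either. For B cell markers the median was −0.357 ± 0.21 and for mast cell markers −0.236 ± 0.206 with time point, with none called, so for these lists time point and burden cannot be told apart, since the SE is too wide. Within the lines numbered in the 1000s the median slope was −0.749 for erythroid and −0.288 ± 0.073 for B cell markers, with 14 of 16 and 9 of 15 called, which argues against the number series for both. For mast cell markers it was −0.42 ± 0.169 with 4 of 15 called, too near the bound set for its SE, which leaves the number series open as part of that fall. RNA of host marrow cells may have been carried into the samples: over 18 lines, log2 globin CPM rose with the log2 odds of non-leukemic cells (slope 0.845 ± 0.099, SE), but over 63 libraries within groups the slope was 0.181 ± 0.103 (permutation p = 0.0521), which leaves this open. How cells were sorted is not stated, so expression by the leukemic cells and host RNA cannot be told apart.

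Genes of chromosome 15 were higher in the M784 and M798 lines than in the T1 lines, by 0.53 in the median. With the chromosome parted into 3 by position, the smallest median was 0.517, which argues against a few genes or 1 region, and after regression on GC content and gene length 0.528 was left. Within the lines numbered in the 1000s the median was 0.511, which argues against the number series. With 95.8% of its genes higher and a median near the 0.585 of 3 copies against 2, a further copy of the chromosome is a candidate explanation. No DNA was analysed here.

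Single libraries lay far from the rest of their group in 4 of 64 tests of 8 measures, where chance alone gives about 1 in 20 groups. The labelled burden of M784 Sapphire T3 replicate 2 was 85.6%, against 69.9% to 71.1% in the others. Total counts were 48.612 M in M800 iRFP T4 replicate 1 against 24.379 M to 27.554 M. In M800 iRFP T2 replicate 2 the most abundant gene, Gm42418, held 5.161% of counts against 1.852% to 2.044%, and the mitochondrial share of M800 iRFP T4 replicate 3 was 2.764% against 2.005% to 2.105%.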

How the results depend on the processing

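The fits with the Erythroid score, with line of descent as a block, without 2 libraries that stood apart and without 4 chromosomes were chosen after the results were seen; the cause of a moved count was not tested. Between libraries no paired analysis was possible because the labels give no replicate numbers that groups share, whereas line sums were paired by line of descent for T3 against T2 and T4 against T3. Of 8230 values of named genes over other settings, 7544 kept direction and call, 600 lost and 59 gained the call and 27 reversed, and of 9482 with 1 library or line left out 8935 kept both, 520 lost and 27 gained the call. Without the 4000s, 1 line of descent was left for T4 against T3 across lines, which gives no value.

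Counts that moved over 1.5 times, beside the main value: with the Erythroid score, T1 iRFP against GFP 1562 (3332), T3 against T2 in M784 Sapphire 1340 (4224), M784 GFP 1164 (4706) and M798 GFP 2141 (5043), T4 against T3 in M784 Sapphire 2093 (4706), iRFP recipients 2311 (9344), burden 1 (469). Score and burden were too closely correlated over lines for that last fit to part them. With only the groups compared, T3 against T2 in M798 Sapphire 73 (112) and M784 GFP 1372 (4706), T4 against T3 in M784 GFP 1 (72) and M800 iRFP 267 (1619), which was 1045 with no low-count filter. Without the 2 libraries, T4 against T3 in M784 GFP 47. Sapphire recipients at T2 alone 1936 (4764). Across lines, T2 against T1 (707) gave 2363 in DESeq2, 8918 with libraries as units and 384 without colour; T3 against T1 (72) gave 1747, 9560 and 203, and 383 in limma-trend, 275 with no filter and 526 without the 4000s. T3 against T2 across lines (0 in edgeR, 1060 unadjusted) gave 131 in DESeq2, 5611 with libraries and 1 with no filter, and T4 against T3 (0, 738 unadjusted) 65, 1898 and 80. Burden (469) gave 14 with time point, 312 with line of descent as a block, 900 in DESeq2, 4 within groups, 8 on log2 burden, 1020 without the 4000s and 0 in edgeR with T2 and T3 lines alone (1839 unadjusted; DESeq2 was not run there). Lists passed in 242 of 672 tests, 4 with an estimated correlation and 240 in fry, 159 of them shared.

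With 1 unit left out, T4 against T3 in M784 GFP ran from 18 to 253 and in M800 iRFP from 753 to 3840, T2 against T1 from 1 to 982, T3 against T1 from 0 to 526, T4 against T3 across lines from 7 to 93 (7 without M800 iRFP, 50 without M784 GFP, 93 without M784 Sapphire) and burden from 261 to 834.

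Log2 values that reversed: for T1 against GMP, Slc4a1 −0.16 in the alternative of M784 GFP T2 against GMP, which holds no T1 library and did not call it. With the Erythroid score, Rsad2 0.10 at T1 iRFP against GFP, Cd74 0.15 in M784 GFP, Gata1 0.17 and Itga2b 0.27 in iRFP recipients, and burden slopes of Tal1 0.0263, Car2 0.0534, Gata1 0.0906 and Ly6g 0.0119. Those burden slopes cannot be told apart from the score, which follows burden over lines and counts Car2 among its members. At T2 alone, Myc 0.0916 in Sapphire recipients, in iRFP recipients Six4 −0.54, Hoxa10 −0.13, Csf1r 0.0826, Kit 0.72, Cd34 1.26 and Mpo 0.39, and in GFP recipients Gp9 −0.54 and Cxcl12 −0.33. At T3 alone, Hoxa9 0.46 in iRFP recipients and Hoxa10 0.11, Itgam 0.33 and Meis1 0.88 in GFP recipients. Within groups, burden slopes of Tnnt1 −0.0029, Atp5k −0.0049, Lamtor4 −0.0126, Dnajc15 −0.0131 and Ly6g 0.15.

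Splits of the same samples were counted with only the groups compared in each fit, the labels included. In 1 of 35 splits each, the labels gave the highest count at T1 for Sapphire against GFP (6501, highest other 1) and against iRFP (7520, 0), and in M784 Sapphire for T3 against T2 (5690, 0) and T4 against T3 (6403, 1). The same held in 1 of 100 for M798 GFP (3861, 1988) and M800 iRFP (5482, 1525) at T3 against T2, Sapphire (6325, 1543), iRFP (8404, 5454) and GFP recipients (7321, 3107) and burden (469, 220), and in 1 of 27 for T2 (707, 0) and T3 (72, 0) against T1. Each is the smallest share its splits allow, without adjustment over comparisons. For libraries it argues against a chance split of these libraries, and says nothing of chance between lines or recipients. Across lines, 1 line left out could remove nearly all calls against T1, and the burden splits took related lines as independent. Chance is therefore not excluded for T2 or T3 against T1 or for burden. In M800 iRFP at T4, 3 of 35 splits gave as many genes (267, highest other 846), so chance is not excluded, and a split with several times the real count points to a structure of these samples. For T3 against T2 across lines all 32 splits gave the same 0 genes in edgeR. Splits are too few for a share under 0.05 in T1 iRFP against GFP (3930, 0), T3 against T2 in M798 Sapphire (73, 1), M784 GFP (1372, 0) and M798 iRFP (6167, 0), each 1 of 10, and T4 against T3 across lines (0, 1), 4 of 4.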

Other observations

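The values in this part were chosen after the results were seen, and no test was made for this part.

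Some genes were near 0 CPM in certain lines and not in others. In M798 iRFP, genes near 0 CPM at T3 but not at T2 included the insulin receptor adaptor Grb14 (0.469 against 63.7), the homeobox genes Hoxa11 (0.249 against 77.1) and Six4 (0.103 against 45), and Igf2r (0.934 against 325). Over 10015 genes centred on the mean of all lines, the T2 and T3 profiles of M798 iRFP correlated at −0.219, against 0.415 to 0.9 for the other 8 consecutive pairs. Hoxa11 in M800 iRFP measured 59.8 CPM at T2, 14.9 at T3 and 3.25 at T4. Ugt8a and Sdk1 were at most 0.122 and 0.191 CPM in the M800 lines. The meiotic recombinase Dmc1 measured 22.6, 55.2 and 61.9 CPM at T2, T3 and T4 of M784 GFP, 2.97 in GMP and at most 0.497 in any other line.

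The endothelial lipase Lipg measured 149 to 359 CPM at T1 and at most 12.3 in later lines. The beta-globin Hbb-bs ranged from 621 CPM in T1 GFP to 0.975 in M800 iRFP T4, with 121 in GMP. Cyclin D2 measured 374 CPM in GMP and 2.78 to 46.2 in leukemic lines. Of the Y-linked genes, Ddx3y was at 30.4 to 37.2 CPM in M784 Sapphire T2 and T4 and M784 GFP T3 and T4, and at 47.6 to 102 in the other leukemic lines. Xist was at most 0.274 and the T cell gene Cd3e at most 0.124 CPM in any group.

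Chromosome medians against GMP differed within lines of descent too. On chromosome 15 they were 0.219 in M798 iRFP T3 and up to 0.483 in other M784 and M798 lines. On chromosome 6 the median of M798 iRFP was 0.354 at T2 and −0.091 at T3, and on chromosome 12 it was 0.448 at T2. Simulated counts with 3 copies against 2 gave 0.572 where 0.585 was put in.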
